A study of Arabidopsis thaliana with 6 samples.

How the data were processed

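The series held 6 samples of whole Arabidopsis Col-0 seedlings: ENAP1 ChIP, ENAP1-EIN2 reChIP and input, each in air and in ethylene, with 1 library per group. Groups were taken from the sample titles, which match the descriptions; the treatment field of the ethylene samples names air, and the titles were followed. The 4 immunoprecipitated samples had peak lists, and read-level data were not used here.

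Per the labels' protocols, seedlings were grown in the dark at 24 °C for 3 days and treated for 4 hours, and ENAP1 was precipitated with an antibody against green fluorescent protein. BWA and the build TAIR10 are named in the submitters' processing notes. Peaks were called with MACS2 2.1.0.20150603, per the file headers, for each library against a single control library, with a p cutoff of 0.01, a genome size of 120000000 bp, a mapping quality named as 30, and at most 1 tag kept per position; no libraries were pooled. Per the file headers, the air ENAP1 ChIP and the air reChIP were called against the same control library, the ethylene ENAP1 ChIP against another, and the ethylene reChIP against the air reChIP library. The ethylene reChIP list therefore measures a difference between immunoprecipitations and not occupancy over input. Each list gives, as deposited by the authors, the pileup at the summit as a signal in tags (scaled to the smaller library), the −log10 of the p-value and of the q-value, and the fold enrichment as a ratio over the local control. The headers state that q would not be calculated, yet the q column holds values, and these were used.

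Total tags were 13284188 (ENAP1 ChIP, air), 13273018 (ENAP1 ChIP, ethylene), 3959931 (reChIP, air) and 1844488 (reChIP, ethylene), per the file headers, of which 37%, 34%, 84% and 83% were duplicates. The control libraries held 7160364 tags (air) and 4809861 tags (ethylene) after filtering. Most reChIP peaks rested on few tags: 72.3% of the air and 79.9% of the ethylene reChIP peaks had a pileup of 5 or less.

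Peaks lay on chromosomes 1 to 5 only, and all were used. Peaks were compared by overlap of at least 1 bp, as a share of each list with an exact binomial 95% interval, beside 1000 random placements on the same chromosome and 1000 moves of each peak to a random edge of a random protein-coding gene at the same signed distance. Genes came from a RefSeq table of assembly TAIR10.1, which pairs locus tags with symbols and gene positions but was used without strand, exons or a transposable element class; none of its coordinates are printed. Its register with the peaks was checked by shifting it by 1000 to 10000 bp: each chromosome was split at its middle, and in 10 of 10 parts the unshifted table gave the highest share of air ENAP1 summits within 200 bp inside a gene edge (34.2 to 44.8%, at most 11.6% when shifted). A target was 1 of 27444 protein-coding genes with a summit inside it or within 1000 bp. The planned windows relative to gene starts, the exon and untranslated region classes and transposable element genes were replaced by windows on both sides, distances to gene edges and the pseudogene class; motif searches were not made, because no genome sequence was used here.

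The 10 gene lists, with 191 genes that all matched the table, the pairs of lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the highest fold per library (1 gene per peak, the nearest), the 5 highest shared and single-list targets of each of 4 pairs, up to 4 highest targets per gene list and library, and ENAP1, EIN2, EIN3, EBF1, EBF2, ETR2, ERF1 and HLS1; further list members that are named only as targets were chosen after their values were seen. A list's count of targets was set among 10000 random lists of the same size matched on gene length in 10 classes. For its percentile, random lists with an equal count were split evenly between lower and higher. On simulated lists of 20 genes for the air ENAP1 ChIP targets among 27444 genes, 4.5% of 200 unchanged lists lay outside the central 95%, and 91.0% of lists with 60% of the other members planted lay above the 97.5th percentile. Such percentiles and placements describe these libraries and are not tests across replicates.

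The control level under a peak was computed from the deposited pileup and fold as (pileup + 1) / fold − 1; its lowest value in the air reChIP list, 0.601, equals the genome background of 0.601 that follows from the tags, fragment length of 112 bp and genome size in the header. In the ethylene reChIP list that control was the air reChIP library, so the level there reflects air reChIP signal. A level of at least 5 times the median of its list was called high. This limit was chosen after 3, 5 and 10 times the median had all been looked at, and a verdict was kept only where all 3 gave it. Alternatives were −log10 q of at least 5, fold at or above the list median, the same number of peaks per list (8858), overlap of at least 50% of both peaks, summits at most 100 bp apart, peak midpoints and unmatched random lists, and, added after the data were seen, q of 0.05 or lower, no pseudogene peaks, windows of 500 bp, the nearest gene only, the ENAP1 ChIP list of the other treatment, no peaks at 8 genes, no peaks at a high control level, random placements under each setting and in each class of q, the signalling list without EIN2 and EIN3, and the reChIP pair without the peaks in doubt. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.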

Results

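ENAP1, a nuclear protein that associates with EIN2, was mapped on the chromatin of Arabidopsis Col-0 seedlings grown for 3 days in the dark and then kept for 4 hours in hydrocarbon-free air or in air with 10 ppm ethylene. EIN2 is the membrane protein that passes the ethylene signal from the endoplasmic reticulum to the nucleus. In ENAP1 ChIP, chromatin was precipitated with an antibody against green fluorescent protein; in ENAP1-EIN2 reChIP, that material was precipitated again with an antibody against EIN2, so that DNA carrying both proteins was sought. The data were 4 peak lists, 1 for each assay and treatment, and 2 further libraries were inputs. With 1 library per group, no value below had a replicate check, and no p-value across genes or peaks was computed. The ENAP1 ChIP libraries kept 8400099 (air) and 8811720 (ethylene) tags after removal of duplicates, the reChIP libraries 644263 (air) and 304818 (ethylene), which was 13.0 and 28.9 times fewer than the ENAP1 ChIP library of the same treatment. Intervals are exact binomial 95% intervals and cover counting error only. Fold enrichment is the authors' own value for each peak and was used only within a list.

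The first question was where ENAP1 lay in air and in ethylene. All 5 ethylene receptor genes, ETR1, ERS1, ETR2, EIN4 and ERS2, were ENAP1 targets in both treatments, a target being a protein-coding gene with a peak summit inside it or within 1000 bp of it. Of all protein-coding genes, 38.6% were targets in air and 36.4% in ethylene. The peaks at ERS2 (2.16-fold in air, 2.18-fold in ethylene) and at ERS1 in ethylene (2.32-fold) lay under the median fold of their lists (2.69 in air, 2.86 in ethylene). The strongest peak of the ethylene list lay in ETR2 (AT3G23150; 3:8254370-8254908) with 17.4-fold enrichment, and the air list had a 13.6-fold peak at the same place (3:8254476-8254944). In air the strongest peak lay in the phosphofructokinase gene PFK6 (AT4G32840; 4:15848294-15848664; 16.5-fold). Genes that were among the 10 highest of both lists were ETR2, AT3G58130, APD1 and AT3G06660. The lists held 9712 peaks in air and 8858 in ethylene, with median widths of 267 and 257 bp, and 95.5% and 92.0% of them had a q of 0.05 or lower.

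Other high peaks of the air list lay in NIG (14.2-fold), in NUDT5 (14.2-fold), which encodes a Nudix hydrolase, in AT3G10040 (14.1-fold), and beside AT1G19430 (13.9-fold) and PRA1.F4 (13.9-fold). In ethylene they lay beside RALFL22 (15.5-fold), a gene for a small secreted peptide, beside AT5G04250 and the prohibitin gene PHB2 (13.6-fold), and in AT4G19220, AT1G50290 and AT1G11200 (14.5-, 14.0- and 14.0-fold). At the ENAP1 gene itself (AT3G11100) the fold of the ENAP1 ChIP peaks was low, 2.01 in air and 2.19 in ethylene, though their pileups of 174 and 111 tags lay above the list medians of 46.9 and 33.8; the control level there was 6.14 and 5.38 times the median.

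ENAP1 summits gathered just inside gene edges. In air 39.3% of summits (95% interval 38.3 to 40.2) and in ethylene 41.3% (40.3 to 42.4) lay inside a protein-coding gene and within 200 bp of its edge, against 8.57% of random positions. Pseudogenes held 0.309% of the air summits and 0.237% of the ethylene summits, against 8.01% of random positions. The reChIP summits were closer to the random share at gene edges, with 11.5% in air (10.8 to 12.1) and 14.2% in ethylene (13.5 to 14.9), and 3.26% and 6.34% of them lay in pseudogenes. Among the ethylene reChIP peaks with −log10 q of at least 5, 33.1% lay inside a gene and within 200 bp of its edge. Starts and ends of genes were not told apart, because strand was not used here.

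**Figure D1:**
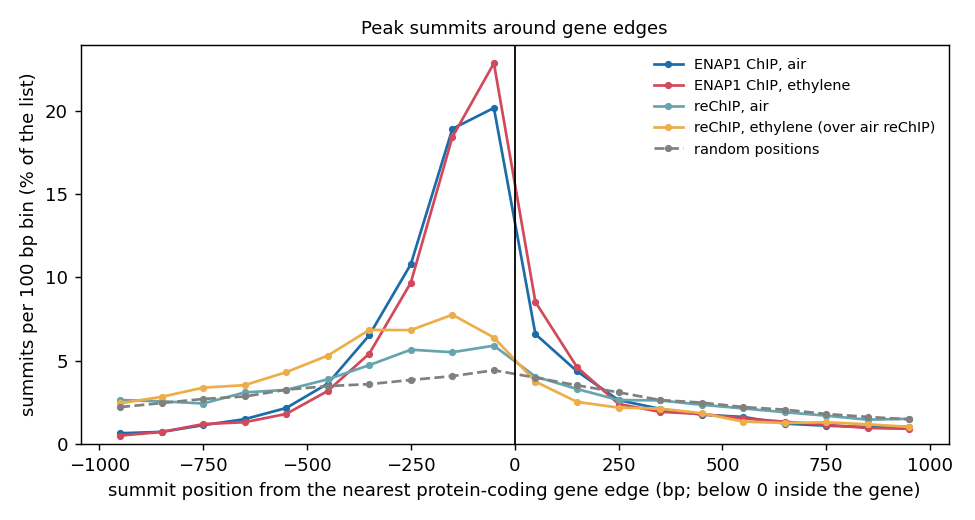
Share of peak summits (%) in 100 bp bins by position from the nearest protein-coding gene edge (bp, below 0 inside the gene), with 1 line per peak list and a dashed line for 100000 random positions. Both ENAP1 ChIP lines peak in the 200 bp inside the edge, which hold 39.3% and 41.3% of summits, while the reChIP lists have 11.5% and 14.2% there, against 8.57% of random positions.

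ENAP1 ChIP peaks lay at largely the same sites in air and in ethylene. No control precipitation with the antibody against green fluorescent protein was among the samples. Antibody background shared by both treatments was therefore not excluded. Of the 8858 ethylene peaks, 79.5% (78.7 to 80.4) overlapped an air peak, against 4.84% for random placements and 10.9% for moves to random gene edges, and 72.3% (71.4 to 73.2) of the air peaks overlapped an ethylene peak. The overlap was 96.0% for ethylene peaks with −log10 q of at least 5 and 47.0% for those with q above 0.05. Target genes numbered 10605 in air and 9993 in ethylene, and 8656 were shared, where independent lists would share 3862. Shared genes with the highest ethylene peaks were ETR2, AT3G06660, RALFL22, APD1 and AT5G04250.

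A further 1337 genes were targets in the ethylene list alone and 1949 in the air list alone, and no test of these differences was possible. The ethylene peaks that gave AT1G48750 (4.90-fold), AT1G63290 (4.83-fold) and HMT-1 (4.53-fold), a homocysteine methyltransferase gene, overlapped no air peak. RAD9 (6.82-fold) and BT2 (4.29-fold) were also counted for ethylene alone, but their peaks overlapped an air peak whose summit lay outside their windows. The highest peaks at genes counted for air alone lay at AT1G23950 (5.11-fold), AT4G34960 (4.86-fold), AT1G74460 (4.60-fold), WRKY38 (4.30-fold), which encodes a WRKY transcription factor, and CSLA11 (4.22-fold), and none of them overlapped an ethylene peak.

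In ethylene, genes of ethylene signalling were ENAP1 targets more often than random lists matched on gene length. The random lists were not matched on expression, and abundantly transcribed housekeeping genes stood higher in the same library (percentile 99.9). Whether the excess is particular to ethylene signalling was not tested. Of 21 receptor and signalling genes, 15 were targets in ethylene (percentile 99.7 among the random lists). In air 12 were targets (percentile 88.3), all of them among the 15. Those in ethylene alone had low peaks: RTE1 (2.86-fold), RTH (2.31-fold) and RAN1 (1.74-fold, with q above 0.05). Besides the receptors, the 12 held CTR1, the kinase that holds the pathway off, EIN2 (9.03-fold in air, 5.50-fold in ethylene), the transcription factor gene EIL1, the F-box gene EBF1 and the exoribonuclease gene EIN5 (6.45-fold in air, 7.14-fold in ethylene). ETR1 had a 7.92-fold peak in air and a 4.82-fold peak in ethylene. No ENAP1 peak lay at EIN3, the main transcription factor of the pathway, or at EBF2. With only peaks of −log10 q of at least 5, the ethylene list held 8 of the 21 genes, at percentile 89.5.

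Of 24 ethylene response genes, 14 were ENAP1 targets in air (percentile 98.8) and 9 in ethylene (percentile 68.2), and 8 were targets in both. They included ERF4 (4.31-fold in air, 2.65-fold in ethylene), ERF104 (4.04-fold in air), ERF6 (3.75-fold in air, 2.82-fold in ethylene) and ERF1 (2.56-fold in air, 3.26-fold in ethylene), genes for AP2/ERF transcription factors. HLS1, which controls the apical hook, had no peak in any list. The air percentile fell to 97.3 against random lists with no length matching and to 85.4 with peaks at or above the median fold, and the difference between the treatments was not tested.

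Among the other lists fixed before the data were examined, the abundantly transcribed housekeeping genes stood highest, with 15 of 19 members in ethylene (percentile 99.9) and 11 in air (percentile 88.2). Their highest peaks lay at the actin genes ACT8 (9.87-fold in air, 5.39-fold in ethylene) and ACT2 (6.96-fold in air, 7.28-fold in ethylene). EF1A-A2 and EF1A-A3 were both counted from the same peak in each treatment, and the ethylene peak at ACT7 had q above 0.05. Floral and meristem regulators stood lowest, with 2 of 14 in ethylene (percentile 1.53), AP1 and FLC, and 5 in air; that percentile left the lower tail with windows of 500 bp (3.17), the nearest gene only (7.69) and unmatched random lists (4.2). Of 21 nuclear photosynthesis genes, 4 were targets in air and 3 in ethylene, with LHCA3 the highest (3.38- and 3.04-fold). Seed storage and maturation genes gave 6 of 16 in each treatment, with EM6, a late embryogenesis gene, at 9.33-fold in air and 7.83-fold in ethylene. Ethylene biosynthesis genes gave 7 of 16 in each, with ACO1 the highest (3.89- and 3.60-fold). Auxin genes gave 9 and 11 of 23, led by ARF8 (6.14- and 7.53-fold). Light signalling genes gave 6 and 7 of 16, led by HY5 (4.64- and 4.68-fold), and histone acetyltransferase and deacetylase genes 10 and 11 of 21, led by HAF1 in air (5.58-fold) and HAC5 in ethylene (4.38-fold). Over the 10 lists and 4 libraries, 3 of 40 percentiles lay above the central 95% of random lists and 1 below it, where chance alone gives 2 outside.

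**Figure D2:**
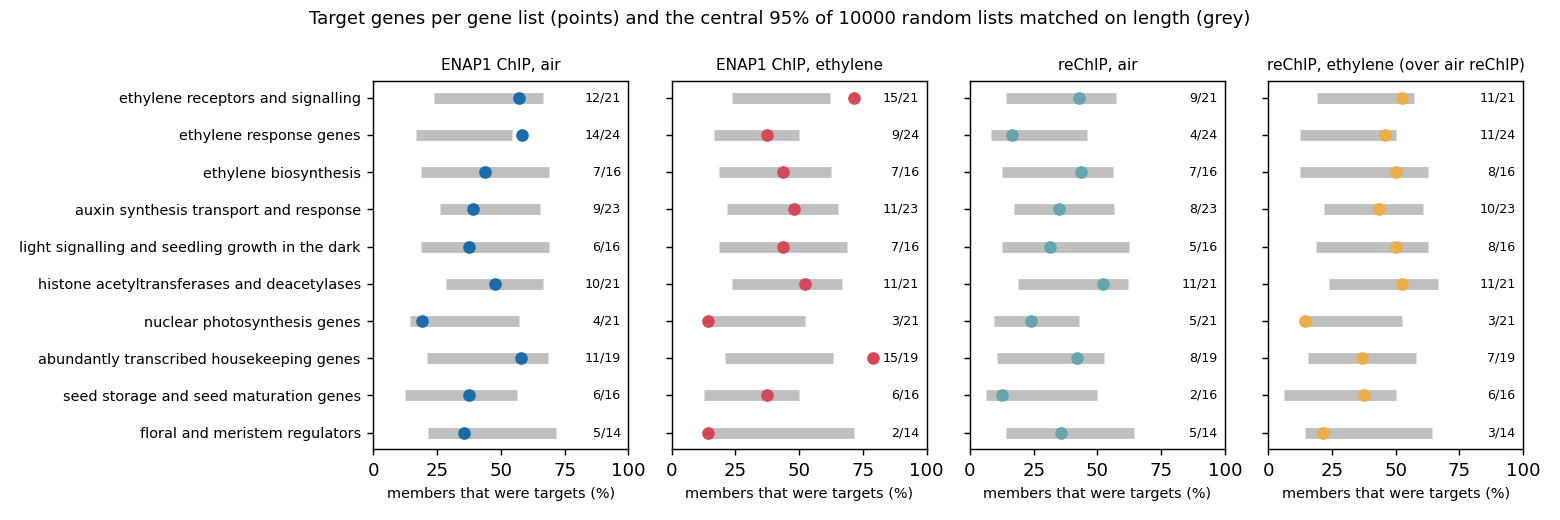
Share of each gene list's members (%) that were targets, with 1 panel per peak list. Points are the observed shares with the counts beside them, and grey bars span the central 95% of 10000 random lists matched on gene length. In the ethylene ENAP1 ChIP panel, 15 of 21 ethylene signalling genes and 15 of 19 housekeeping genes lie to the right of the bars.

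The highest peak of the air reChIP list was a 52.5-fold peak in ABI5 (AT2G36270; 2:15206195-15207450), the gene of a bZIP factor of abscisic acid signalling. The next was a 34.6-fold peak of 3128 bp in EIN2 itself (AT5G03280; 5:789969-793096), where peaks covered 70.4% of the gene. Others lay in EMB2771 and its neighbour AT5G05550 (16.1-fold), in the sirtuin gene SRT2 (13.2-fold), in AT2G31590 (11.8-fold), in AT3G41762, in AT5G10340 (10.6-fold), in ENAP1 (10.4-fold), in B ALPHA (10.4-fold), which encodes a protein phosphatase 2A subunit, and beside AT2G07739 (9.49-fold). EIN3 had a 5.80-fold peak, and a 12.6-fold peak (3:14201424-14201808) had no protein-coding gene within 1000 bp. The list held 9174 peaks of median width 121 bp and median pileup of 5 tags, and 19.4% had a q of 0.05 or lower. Only 87 peaks had −log10 q of at least 5, and 50 of these lay where the control level was at least 5 times the median of the list, a limit set after the data were seen.

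The question of the reChIP in air was whether EIN2 was found at ENAP1 sites before ethylene was given. Of the 9174 air reChIP peaks, 1039 (11.3%) overlapped an air ENAP1 ChIP peak, against 3.68% for random placements and 5.81% for moves to random gene edges. The highest of the shared targets were ABI5, EIN2, EMB2771, AT2G31590 and ENAP1, and each of these reChIP peaks overlapped an ENAP1 ChIP peak. At EIN2 the 34.6-fold reChIP peak overlapped only weak ENAP1 peaks (1.89- and 1.94-fold) and not the 9.03-fold one. A lower reChIP peak (5:793568-793773; 5.86-fold) lay inside that 9.03-fold ENAP1 peak. Whether the signal at ABI5, EIN2, EMB2771 and ENAP1 came from chromatin was not settled, since cloned DNA of such genes was not excluded, and the ENAP1 peak lay at 9.92 times the median control level. The peaks in SRT2, AT3G41762 and AT5G10340 and beside AT2G07739 and AT3G29763 (9.39-fold) overlapped none, and these genes were no ENAP1 targets in air; all of these peaks but that in SRT2 lay at a high control level (9.11 to 23.6 times the median), where DNA of many copies was not excluded. Conversely the ENAP1 peaks at AT3G10040, ETR2, GATB (13.2-fold), AT5G04250 (13.1-fold) and AT1G08910 (12.9-fold) had no air reChIP peak. Targets in common numbered 3912, where independent lists would share 3231. Both air lists were called against the same input, but the overlap with the ethylene ENAP1 ChIP list, which had another input, was 10.1% against 3.27% for random placements, a ratio of 3.10 beside 3.08 with the shared input. The air overlap was 9.31% for peaks with q above 0.05, 35.4% (27.2 to 44.4) for −log10 q of 3 to under 5, and 18.4% (10.9 to 28.1) for at least 5.

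By list, the air reChIP targets held 9 of 21 signalling genes (EIN2, EIN3, RTH and RTE1 the highest), 4 of 24 response genes (ERF6, PORB, ERF104 and PIF3), 7 of 16 biosynthesis genes (ACS6 at 4.07-fold), 8 of 23 auxin genes (IAA3 at 3.75-fold), 5 of 16 light signalling genes (FAR1 at 5.62-fold), 11 of 21 histone acetylation genes (SRT2, then HD2A at 4.64-fold), 5 of 21 photosynthesis genes (RBCS1A at 4.37-fold), 8 of 19 housekeeping genes (ACT8 at 4.91-fold), 2 of 16 seed genes and 5 of 14 floral genes (AP1 at 4.37-fold). The percentile of every list lay within the central 95% of random lists. Most of these targets rested on peaks with q above 0.05, among them all those of the response, auxin and seed lists; with q of 0.05 or lower there remained 5 signalling genes (EIN2, EIN3, RTH, RTE1 and CTR1), 3 housekeeping genes (ACT8, GAPC2 and ACT2), 2 histone acetylation genes (SRT2 and HD2A) and 1 each of the biosynthesis, light, photosynthesis and floral lists (ACS6, FAR1, RBCS1A and AP1). Cloned DNA was not excluded for EIN2, EIN3 and SRT2.

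The ethylene reChIP list was called with the air reChIP library as its control, so its peaks mark DNA that was more abundant in the ethylene reChIP than in the air reChIP. Its strongest peaks lay in AT2G32150 (2:13660332-13660594; 10.2-fold), AT5G14850 (9.66-fold), AT5G19120 (9.62-fold), AT2G13660 (9.48-fold), AT1G01300 (9.22-fold) and HUB2 (9.02-fold), a gene for histone H2B ubiquitination. ETR2 followed with an 8.82-fold peak (3:8254600-8254769) inside the ENAP1 peak of that gene, with AT4G22530 and AT5G63080 at the same fold and AT1G11200 at 8.75-fold. The light signalling factor HY5 had an 8.37-fold peak (5:3594242-3594458), the histone deacetylase gene HD2D a 7.39-fold peak and ERF6 a 7.38-fold peak (4:9752936-9753235). The list held 9881 peaks of median width 158 bp and median pileup of 4 tags, 57.5% of them had a q of 0.05 or lower, and 133 had −log10 q of at least 5.

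In ethylene, the reChIP peaks with the lowest q lay mostly at ENAP1 sites. The overlap with the ethylene ENAP1 ChIP list was 79.7% (71.9 to 86.2) for the 133 peaks with −log10 q of at least 5, 51.8% (47.8 to 55.8) for −log10 q of 3 to under 5, 19.2% for weaker peaks with q of 0.05 or lower and 8.32% for q above 0.05. Over the whole list it was 17.4% (16.7 to 18.2), against 3.60% for random placements and 5.89% for moves to random gene edges. Targets in common numbered 4482, where independent lists would share 3397, and 4007 genes were targets of both ENAP1 ChIP lists and of the ethylene reChIP. The highest reChIP peaks at shared targets were those in AT2G32150, AT5G14850, AT5G19120, AT2G13660 and AT1G01300, and all but that in AT5G19120 overlapped an ENAP1 peak. The highest at genes that were no ENAP1 targets in ethylene lay in AT4G22530, AT1G72100 (8.09-fold), AT5G41770 (7.29-fold), AT2G16676 (7.28-fold) and AT1G49700 (6.79-fold). Strong ENAP1 peaks at AT3G06660, APD1, AT4G19220, PHB2 and AT3G27220 had no reChIP peak. In this list that means no called gain over the air reChIP, and not absence of EIN2.

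**Figure D3:**
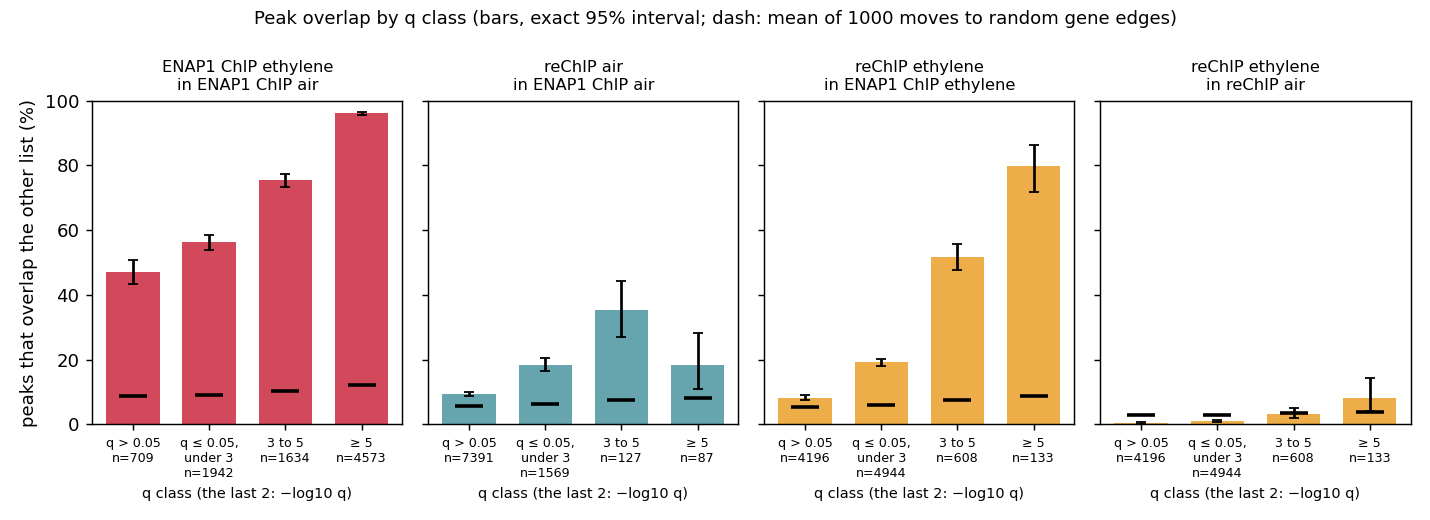
Share of peaks (%) that overlap the other list by at least 1 bp, for 4 pairs of lists and 4 classes of q (1 bar each, with the exact 95% interval; n is the number of peaks). Black dashes give the mean of 1000 moves of the peaks to random gene edges. The share rises to 96.0% for ENAP1 ChIP and to 79.7% for the ethylene reChIP in the class with −log10 q of at least 5, and is 18.4% for the air reChIP in that class; for the reChIP pair it is 0.453% for q above 0.05 and 8.27% in the class of at least 5.

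By list, the ethylene reChIP targets held 11 of 21 signalling genes (percentile 89.3), with ERS2 at 4.38-fold, EBF1 at 4.11-fold and EIN2 at 4.69-fold after ETR2, and 9 of the 11 were also ENAP1 targets in ethylene. The highest reChIP and ENAP1 peaks overlapped at ETR1, ETR2 and EBF1. At ERS1, ERS2, CTR1, EIN2, EIN5 and ARGOS they lay apart. EIN3 (2.78-fold) and EBF2 (2.92-fold) were reChIP targets without an ENAP1 peak, though the EBF2 peak rested on a pileup of 3 tags with q above 0.05, and ERF1 had an ENAP1 peak without a reChIP peak. They held 11 of 24 response genes (percentile 94.0), with ERF4 (5.43-fold), ERF104 (5.39-fold) and ESE3 (4.72-fold) after ERF6. Light signalling gave 8 of 16 genes, HY5, PIF5 (6.17-fold), PIF1 (5.84-fold) and CRY2 (5.34-fold) the highest. Histone acetylation genes gave 11 of 21, HD2D, SRT2 (6.73-fold), HAG1 (5.11-fold) and HDA19 (4.95-fold) the highest. The others gave 8 of 16 biosynthesis genes (ACO4 at 5.68-fold), 10 of 23 auxin genes (ARF19 at 4.11-fold), 7 of 19 housekeeping genes (GAPC1 the highest), 6 of 16 seed genes (EM1 at 4.33-fold), 3 of 21 photosynthesis genes (PSAD1 at 3.98-fold) and 3 of 14 floral genes (FLC at 3.53-fold). No percentile lay outside the central 95%. With −log10 q of at least 5, ETR2 and EIN2 remained of the signalling genes, at percentile 99.4, which rests on 2 genes. The EIN2 peak lay at 138 times the median control level, that is, at high air reChIP signal, and cloned DNA was not excluded for it. With EIN2 and EIN3 left out of the list the percentile was 93.2.

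Direct comparison of the reChIP lists was limited by that control. Of the ethylene reChIP peaks 1.05% (0.861 to 1.27) overlapped an air reChIP peak, against 2.58% for random placements, whose lowest value was 1.99%. The deficit lay in the peaks of weak q: the share was 0.453% for q above 0.05 and 1.09% for weaker peaks with q of 0.05 or lower, both under the random range, but 3.29% (2.02 to 5.03) for −log10 q of 3 to under 5 and 8.27% (4.20 to 14.3; random mean 3.29%) for at least 5, both within it. With −log10 q of at least 5 in both lists, the share was 6 of 133 (4.51%), above every random placement (mean 0.0496%). Without the 8 genes for which cloned DNA was not excluded it was 2 of 129 (1.55%), equal to the highest random placement (mean 0.0372%). It was 0 of 122 without peaks at a high control level. Since the control was the air reChIP library, that filter removes ethylene peaks with high air reChIP signal and lowers this overlap by its construction. Of the 11 ethylene peaks with −log10 q of at least 5 that overlapped any air reChIP peak, 1 lay in EIN2 and 3 in SRT2, both among those 8 genes. A high control level was found at 7 of the 11, which restates their air reChIP signal. Target genes in common numbered 2737, where independent lists would share 2842. Genes that were targets in both, AT2G32150, AT5G14850, AT1G03440 (8.68-fold), HY5 and BSK9 (8.09-fold) being the highest in ethylene, had those ethylene peaks at places with no air peak. Targets of the ethylene list alone with the highest peaks were AT5G19120, AT2G13660, AT1G01300, HUB2 and ETR2, and those of the air list alone were ABI5, AT5G10340, B ALPHA, AT3G29763 and AT2G07565 (8.82-fold). EIN2 had peaks in both lists, the ethylene peak (5:791045-793113; 4.69-fold) lying above the already high air signal.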

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

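The count of tRNA genes, a class outside the gene lists and target counts above, was chosen after the data were seen. What drew attention was that peaks lay beside them more often than random placements of the same peaks. Of 625 tRNA genes, 65 had an air ENAP1 ChIP summit within 200 bp, against a mean of 23.2 and a highest value of 34 over 200 random placements. In ethylene ENAP1 ChIP 75 tRNA genes did, against a mean of 21.9 and a highest value of 36. In the air reChIP the number was 42 (mean 22.1, highest 34), and in the ethylene reChIP it was 33 (mean 24.4), which lay inside the random range of 14 to 36. The excess in ENAP1 ChIP was not particular to tRNA genes. Of 3480 long noncoding RNA genes, 481 had such a summit in air (mean 253, highest 297) and 451 in ethylene (mean 231, highest 269). The counts for snoRNA and miRNA genes lay inside the random range in every list.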

How the results depend on the processing

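The overlap of the reChIP pair reversed against random placements, from 1.05% (random range 1.99 to 3.08%) to 4.51% (6 of 133 peaks) with −log10 q of at least 5 (above every random placement, mean 0.0496%). Without the 8 genes in that setting it was 1.55% (2 of 129), equal to the highest random placement (mean 0.0372%). The reversal thus rested on few peaks, some of them at genes for which cloned DNA was not excluded. Without peaks at a high control level the overlap was 0% (0 of 122), with or without the 8 genes. That 0 cannot speak to DNA of many copies, because the filter removes ethylene peaks with high air reChIP signal. The settings q of 0.05 or lower, no pseudogene peaks, 500 bp windows, nearest gene, other-treatment list, no peaks at 8 genes and no peaks at a high control level, random placements under each setting, and the signalling list without EIN2 and EIN3, were chosen after the data were seen. No paired analysis was possible because each group held 1 library, and for that reason no library was left out. Motif searches, the 500 bp promoter, windows relative to gene starts and transposable element genes were not run. Where a setting keeps fewer peaks, that filter lowers the counts by its construction; for the other changes the cause was not tested. The depth of the reChIP libraries, the single library per group and the air reChIP library as control all limit these results.

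With −log10 q of at least 5, the peaks were 5777 and 4573 (ENAP1 ChIP, air and ethylene) and 87 and 133 (reChIP, air and ethylene); targets were 6136 (ENAP1 ChIP, ethylene), 61 and 194 (reChIP). Overlap was 88.2% (ENAP1 ChIP, ethylene in air), 17.2% (reChIP in ENAP1 ChIP, air) and 72.2% (the same, ethylene), and gene edges held 46.6% and 48.3% of ENAP1 ChIP and 33.1% of ethylene reChIP summits. The signalling list fell to percentile 89.5 in ethylene ENAP1 ChIP and rose to 99.4 in the ethylene reChIP, with ETR2 and EIN2, and stood at 93.2 there with EIN2 and EIN3 left out of the list.

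With fold at or above the median, in the same order, peaks were 4857, 4430, 4688 and 5319, and targets 6224, 5780, 4846 and 5814. Overlap was 77.0% (ENAP1 ChIP), 0.846% (reChIP pair) and 14.9% (ethylene reChIP in ENAP1 ChIP), edge shares were 47.6%, 47.9%, 12.6% and 17.1%, and the response list fell to percentile 85.4 in air ENAP1 ChIP. It stood at 97.3 there against unmatched random lists.

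With q of 0.05 or lower, reChIP peaks were 1783 (air) and 5685 (ethylene) and targets 1941 and 6169. Overlap was 80.9% (ENAP1 ChIP), 0.827% (reChIP pair, within the random range of 0.299 to 0.862%), 19.2% (reChIP in ENAP1 ChIP, air) and 23.3% (ethylene), and edge shares were 42.7% (ethylene ENAP1 ChIP), 14.6% and 17.2% (reChIP). The signalling list rose to percentile 98.5 in the air reChIP, with EIN2, EIN3, RTH, RTE1 and CTR1, and stood at 86.5 with EIN2 and EIN3 left out of the list.

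With equal numbers of peaks, overlap was 76.6% (ENAP1 ChIP) and 18.3% (ethylene reChIP in ENAP1 ChIP), and the air ENAP1 ChIP edge share was 40.7%; by peak midpoint it was 40.6%. Overlap of 50% of both peaks gave 71.6%, 0.445%, 2.74% and 8.90% for the 4 pairs (ENAP1 ChIP, reChIP, air, ethylene), and summits within 100 bp gave 73.4%, 0.800%, 7.91% and 13.3%. The ENAP1 ChIP list of the other treatment gave 10.1% (air reChIP) and 18.4% (ethylene reChIP). Without pseudogene peaks, the ethylene reChIP overlap was 18.5% and its edge share 15.2%. Without peaks at a high control level, overlap was 0.543% (reChIP pair) and 16.5% (ethylene reChIP in ENAP1 ChIP). For the reChIP pair that filter removes ethylene peaks with high air reChIP signal, so it lowers the overlap by its construction. By nearest gene, the response list rose to percentile 98.2 in the ethylene reChIP, with 10 genes. Without peaks at 8 genes, EIN2 and EIN3 among them, all 16 values stayed within their criterion, but the signalling list fell from percentile 74.7 to 42.0 in the air reChIP and from 89.3 to 64.0 in the ethylene reChIP. That fall is partly built in, because EIN2 and EIN3 stayed in the list without peaks. With both left out of the list it stood at 56.8 (air) and 78.6 (ethylene).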

Other observations

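The gene families, the control level and the genes outside the naming rule were chosen after the data were seen, as were the tests below of DNA of many copies, of cloned genes, of placement at gene edges and of the control library. The tests at tRNA genes and by fold of ENAP1 peaks were set before their results were seen, but the reading of the tRNA test was changed afterwards. Earlier tests were replaced once their results were known: of 13 air reChIP peaks of at least 10-fold, 5 overlapped an air ENAP1 ChIP peak (38.5%, 13.9 to 68.4), peak length in 8 genes was 50.5 times that in their flanks, and a test of chance calls used the same 1.05% as the last paragraph. Families were taken from gene symbols shared by at least 15 protein-coding genes. Of 94 families, 7 lay above and 13 below the central 95% of random lists in air ENAP1 ChIP, and 7 and 12 in ethylene, where chance gives 4.7 outside. ERF transcription factor genes stood high, with 18 of 25 as ENAP1 targets in air (random mean 8.14) and 15 in ethylene. So did the RABA small GTPase genes of vesicle traffic (17 and 15 of 21), the SYP syntaxin genes (17 and 16 of 23) and the WRKY factor genes (42 of 67 in air, random mean 27.0, and 34 in ethylene). Cytochrome P450 genes (CYP) stood low, with 63 of 229 in air against a random mean of 95.4 and 60 in ethylene, as did ABCG transporter genes (9 of 42 in each), RLP receptor-like protein genes (13 and 12 of 52) and MYB factor genes (32 and 29 of 120). In the reChIP lists 0 families lay above and 5 below the central 95% in air, and 3 above and 3 below in ethylene, close to the number by chance.

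The strongest ENAP1 sites had reChIP peaks most often in both treatments. In air, 29.7% (26.9 to 32.7) of the 10% of ENAP1 ChIP peaks with the highest fold overlapped an air reChIP peak, against 4.22% (3.04 to 5.68) of the 10% with the lowest fold; peak width was not matched. In ethylene the trend was not even: the 10% with the lowest fold overlapped in 19.2% (16.6 to 21.9), and a class of 10% above it in 13.4% (11.3 to 15.9). At the ENAP1 gene itself, the control level was 6.14 times the list median in air ENAP1 ChIP, the second highest of 9712 peaks, and 5.38 times in ethylene. SRT2 had no ENAP1 ChIP peak in air, while in ethylene ENAP1 ChIP peaks covered 52.4% of the gene and none of its flanks. In 8 genes picked for their long or high air reChIP peaks (EIN2, EIN3, ABI5, SRT2, ENAP1, AT5G05550, B ALPHA and ATB BETA), 10393 bp of peaks lay inside the genes and 206 bp in their flanks.

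Of the 87 air reChIP peaks with −log10 q of at least 5, 16 overlapped an air ENAP1 ChIP peak (18.4%). In ethylene 106 of 133 overlapped (79.7%, 71.9 to 86.2 at any control level). The lists had unlike controls, an input in air and the air reChIP library in ethylene. A high control level therefore does not mean the same in both. Of the 87, 50 lay at a high control level. Of these, 13 lay at 2:3187834-3496571, near the centromere, where a long copy of mitochondrial DNA is known to be inserted. Of the 50, 1 overlapped an ENAP1 peak (2.00%, upper bound 10.6%). That low share cannot decide their source. The air ENAP1 ChIP list, called against the same input, itself had only 9 of 9712 peaks at a high control level. DNA of many copies per genome stays a candidate source of the 50 peaks. Peaks at a high control level were not the whole difference, since 15 of the other 37 overlapped (40.5%, 24.8 to 57.9). This lay under the lower bound of 71.3% for ethylene reChIP peaks not at a high control level. Limits of 3 and 10 times the median gave the same reading (45.2% and 30.8% of the others). Cloned DNA of the 8 genes cannot be told apart as the source of the rest: without them the share was 11 of 24 (45.8%, 25.6 to 67.2), under that bound, and with the limit of 10 times the median 11 of 38 (28.9%, 15.4 to 45.9), which both argue against it, but with the limit of 3 times it was 11 of 19 (57.9%, 33.5 to 79.7), under the ethylene lower bound of 65.3% with an interval that spans it. Fewer sites shared by ENAP1 and EIN2 in air, a weaker air reChIP, or the unlike controls stay open and were not tested, with 1 library each.

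The ethylene reChIP peaks with the lowest q overlapped ENAP1 peaks most often. Placement near the edges of random protein-coding genes is argued against, because the observed 79.7% lay above the highest of 1000 moves to such edges, 16.5%. Placement near the edges of expressed genes was not tested, because the moves used all protein-coding genes. Sites at which most immunoprecipitations give peaks stay open: 0 of the 133 peaks lay within 200 bp of a tRNA gene, and the bound set beforehand would have excluded this cause. That bound was set aside after the count was seen, because random placements gave 0.302 on average, so that 0 is a common count even with 5 times as many. Carry-over of DNA from the first precipitation cannot be told apart from binding of EIN2 at ENAP1 sites, because both would raise the overlap at strong ENAP1 peaks, which was 36.5% (33.3 to 39.7) in the 10% with the highest fold and 19.2% in the 10% with the lowest, and no reChIP without the EIN2 antibody was analysed here.

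Taken whole, the reChIP lists overlapped less often than random placements, with 1.05% of ethylene peaks in air peaks against a random range of 1.99 to 3.08%. This held only for peaks of weak q: with −log10 q of at least 5 the share was 8.27% against a random mean of 3.29%. Of these 11 overlapping peaks 7 lay at a high control level, which restates their air reChIP signal, since that library was the control. Use of the air reChIP library as the control of the ethylene list would give a deficit, since DNA frequent in that library is then less often called. It cannot be told apart from a move of EIN2 between sites on ethylene treatment, because that share is the pattern itself and the ethylene reChIP was not called against an input.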
